A study of Rattus norvegicus with 6 samples.

How the data were processed

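RNA from 6 samples of primary rat OPCs, 3 unstimulated and 3 exposed to fibrinogen for 12 h, was measured on 6 Affymetrix arrays. Per the labels' protocols, cells came from pups on the first days after birth and recovered for 2 days in a medium with N2, B27, NT3 and PDGF, RNA was purified on RNeasy columns with DNase, and cDNA was amplified with NuGEN Ovation Pico WTA V2 and labelled with biotin by NuGEN Encore. The fibrinogen dose was not given in the sources used here. The deposited table holds 1 value per probe set and array. Per the submitters' processing notes, which name RMA and limma without versions, settings or roles, the deposited log2 levels were taken to have been normalized by the authors with RMA, which corrects background, sets the arrays to a common distribution and summarises the probes of a set. That scale was inferred from the deposited values, since the table states neither scale nor centring, and the levels were rounded to 2 decimals by the authors. Such normalization can compress differences, most of all those of dim genes, and its effect could not be varied because scanner files were not used here. A level says nothing of absolute amounts, and levels of different probe sets were not compared as amounts.

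Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No array was a copy of another: at most 3.63% of genes had identical values on a pair of arrays. No columns of other samples were present, and the labels name no batch or date.

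The table has 26312 probe sets, of which 1206 were blank on every array (442 of them paired with a gene, 328 of these with an olfactory or vomeronasal receptor gene) and were left out. Of the 25106 with values, the platform's annotation paired 14700 with 1 gene symbol, 275 with several and 10131 with none, and only the first kind was named. Symbols were checked through Entrez IDs against the RefSeq gene table of assembly GRCr8, where 15064 of the 15094 probe sets with 1 symbol, blank ones included, matched and 0 symbols changed. No genome build of the array design was given in the sources used here, so no coordinates are printed. Where a gene had several probe sets (480 genes), that with the highest mean over all arrays was used, which gave 13949 genes. Genes of near-identical families can share probes, and their values are uncertain. The 956 olfactory and vomeronasal receptor genes served as a measure of background, and no filter on dim genes was applied in the main test.

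Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) as fibrinogen minus control, with no covariates. p-values were adjusted by the Benjamini-Hochberg method over all 13949 genes, with a threshold of 0.05. The SE of a log2 change is the moderated one of that fit, and the SD of a level is over the 3 arrays of a group. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so none was run per gene. Rises and falls are called only from this test.

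The 23 gene lists (targets and components of BMP, TGF-beta, Wnt, Notch, NF-kappaB, interferon and ERK signaling, markers of OPCs, oligodendrocytes and other cells, proliferation, cholesterol synthesis, matrix, adhesion and stress) were drawn up from general knowledge. They share 15 genes. Each list with at least 5 measured members was tested with limma's camera, which compares its genes with all others, at a preset correlation between genes of 0.01, and p-values were adjusted over the 23 lists. With an estimated correlation camera also uses the 4 residual degrees of freedom of the 6 arrays in place of many, so its p-values rise even where the estimated correlation is low (0.00467 for BMP targets). Named genes were 11 fixed ones (Id1, Id2, Id3, Smad6, Smad7, Lef1, Hes1, Mbp, Pdgfra, Olig2 and Gfap), the 10 largest rises and 10 largest falls among genes that passed with groups that did not overlap, and up to 4 members per list with the largest changes that passed, or 2 if none did. One gene taken by this rule is not reported here. Lists, tests, this rule and the alternatives were fixed before the data were examined, with exceptions added after the values were seen. These were a filter at the 95th percentile of the receptor genes, list counts without fibrinogen 2, and the genes Xylt1 and Nes. In the closing section they were the 13 gene families, the further genes named, and the tests of the last 2 paragraphs.

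The procedure was tested on simulated data in which the spread of each gene was taken from these data and was equal on all arrays. The arrays themselves differed, with an SD of all genes about their group mean of 0.146 for fibrinogen 2 and at most 0.0939 for a control. The simulated rates therefore hold for equal spread only, and rates under unequal spread were not tested. Of 13949 genes, 200 were given a known log2 change. A change of 1 was called in 100% of 66 genes, of 0.6 in 98.5% of 67, and of 0.3 in 29.9% of 67, and 9 of 13749 unchanged genes were called. Of 23 simulated lists, all 5 shifted by 0.2 and 0 of the others were called. Genes were drawn independently of each other, so the simulated lists held no correlation between genes. In the data the estimated correlation of the lists ranged from -0.0549 for TGF-beta targets to 0.548 for cholesterol synthesis genes. The simulation therefore cannot tell how often camera at its preset correlation calls unshifted lists of correlated genes.

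Alternatives were quantile normalization, median centring and cyclic loess of the deposited values, 2 filters on dim genes, an intensity trend and a robust prior in eBayes, array weights, the mean of all probe sets of a gene, all probe sets, 3 other thresholds, each array left out, the replicate number as a block, and for lists an estimated correlation, ranks and fry. In the closing section, medians of lists have percentile bootstrap intervals over genes, and unequal change within a list was measured by Cochran's Q with the moderated SEs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.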

Results

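Gene expression was measured on Affymetrix arrays in primary rat oligodendrocyte progenitor cells (OPCs), the dividing precursors of the myelin-forming cells of the central nervous system. The cells came from newborn pups and had recovered in a growth medium holding PDGF and NT3, which keep OPCs dividing. 3 samples were left unstimulated as controls, and 3 were exposed for 12 h to fibrinogen, the clotting protein that enters nervous tissue where blood vessels leak. The title of the series states that fibrinogen switches on bone morphogenetic protein (BMP) signaling in these cells, and links it to poor myelin repair. Values were log2 levels, 1 per probe set and array, and 13949 genes with a name of their own were tested. The median log2 level was 6.39, 6.40 and 6.40 on the control arrays and 6.43, 6.42 and 6.42 on the fibrinogen arrays. As a measure of background, 956 olfactory and vomeronasal receptor genes had a median log2 level of 4.03 and a 95th percentile of 5.53, and 9883 genes (70.9%) had a mean level above that percentile. The number of arrays limited the precision of every value.

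Fibrinogen changed 432 of the 13949 genes, with 252 higher and 180 lower than in unstimulated OPCs (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with a median log2 change of 0.55 among the genes that rose and -0.48 among those that fell, and 18 rose and 15 fell at least 2-fold. The largest rise was that of Hspb1, a small heat shock protein, from a log2 level of 8.26 ± 0.22 to 10.05 ± 0.10 (SD, n = 3 each), a 3.45-fold increase. Cav1, the main coat protein of caveolae, rose 2.68-fold, with a log2 change of 1.42 ± 0.07 (SE) and an adjusted p of 0.000134 in limma. The matrix proteoglycan Bgn rose 2.39-fold, the BMP target Id1 2.38-fold, the astrocyte filament protein Gfap 2.37-fold and the hyaluronan receptor Cd44 2.17-fold. The transcriptional repressor Bhlhe41, the adhesion molecule Igsf11 and the LIM domain protein Crip1 followed, with log2 changes of 1.09, 1.08 and 1.07.

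The largest fall was that of S100a3, a calcium-binding protein, from a log2 level of 7.64 ± 0.27 to 5.68 ± 0.33 (SD, n = 3 each), which left 0.256 of the control level on a linear scale. Tmem255b fell by 1.87 ± 0.08 (SE) on the log2 scale, with the lowest adjusted p of the genes named here (3.94e-05, limma). Lgr5, a receptor for R-spondins, fell by 1.53, the phosphatase gene Ptprr by 1.33, the chemokine receptor gene Ackr3 by 1.28, the cilium-associated Cfap52 by 1.28 and the protein kinase gene Prkcq by 1.26. Gpr20, Tspan8 and Arhgap24 had log2 changes of -1.17, -1.15 and -1.14, and the level of Tspan8 (4.85 ± 0.28 in controls, SD, n = 3) lay below the 95th percentile of the receptor genes. Median centring of the arrays gave 212 genes higher and 228 lower, so that falls outnumbered rises under that setting. Leaving out 1 array gave 184, 156 and 151 changed genes without control 1, 2 and 3, 231 and 280 without fibrinogen 1 and 3, and 436 without fibrinogen 2.

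Direct targets of BMP signaling were shifted upward as a list in camera with its preset correlation (adjusted p = 1.11e-05), but not with an estimated one (adjusted p = 0.0892 with an estimated correlation). Of 26 measured members of the list, 7 rose, 0 fell and 19 did not pass in limma (8 rose and 0 fell adjusted over the list alone, and 9 were higher and 1 lower at an unadjusted p under 0.05), and the median log2 change was 0.13. Id1, Id2 and Id3, which encode inhibitors of the transcription factors that drive differentiation, had log2 changes of 1.25 ± 0.08, 0.89 ± 0.08 and 0.71 ± 0.15 (SE), with adjusted p-values of 0.000293, 0.00149 and 0.0409 in limma. Id1 went from a log2 level of 7.57 ± 0.08 to 8.83 ± 0.11 (SD, n = 3 each), and Hey1, a repressor shared with the Notch list, rose by 0.55 ± 0.07 (SE). The inhibitory Smads Smad6 and Smad7, feedback regulators of the pathway, had log2 changes of 0.26 ± 0.12 and 0.30 ± 0.08 that did not pass (adjusted p = 0.339 and 0.0769, limma), although Smad7 passed when dim genes were left out, and the change of Smad6, at 5.46 in controls below the receptor percentile, was 0.15 without control 1. The list passed in camera in every fit that left out 1 array, where 3 members rose without control 1, control 2 or fibrinogen 3, 4 without control 3 or fibrinogen 1, and 6 without fibrinogen 2. The call for Id3 ended without any array but fibrinogen 2, with adjusted p-values of 0.0911, 0.0759 and 0.0876 without control 1, 2 and 3, and 0.109 and 0.113 without fibrinogen 1 and 3. The title of the series already names this pathway, so the list was not independent evidence of its direction.

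**Figure D1:**
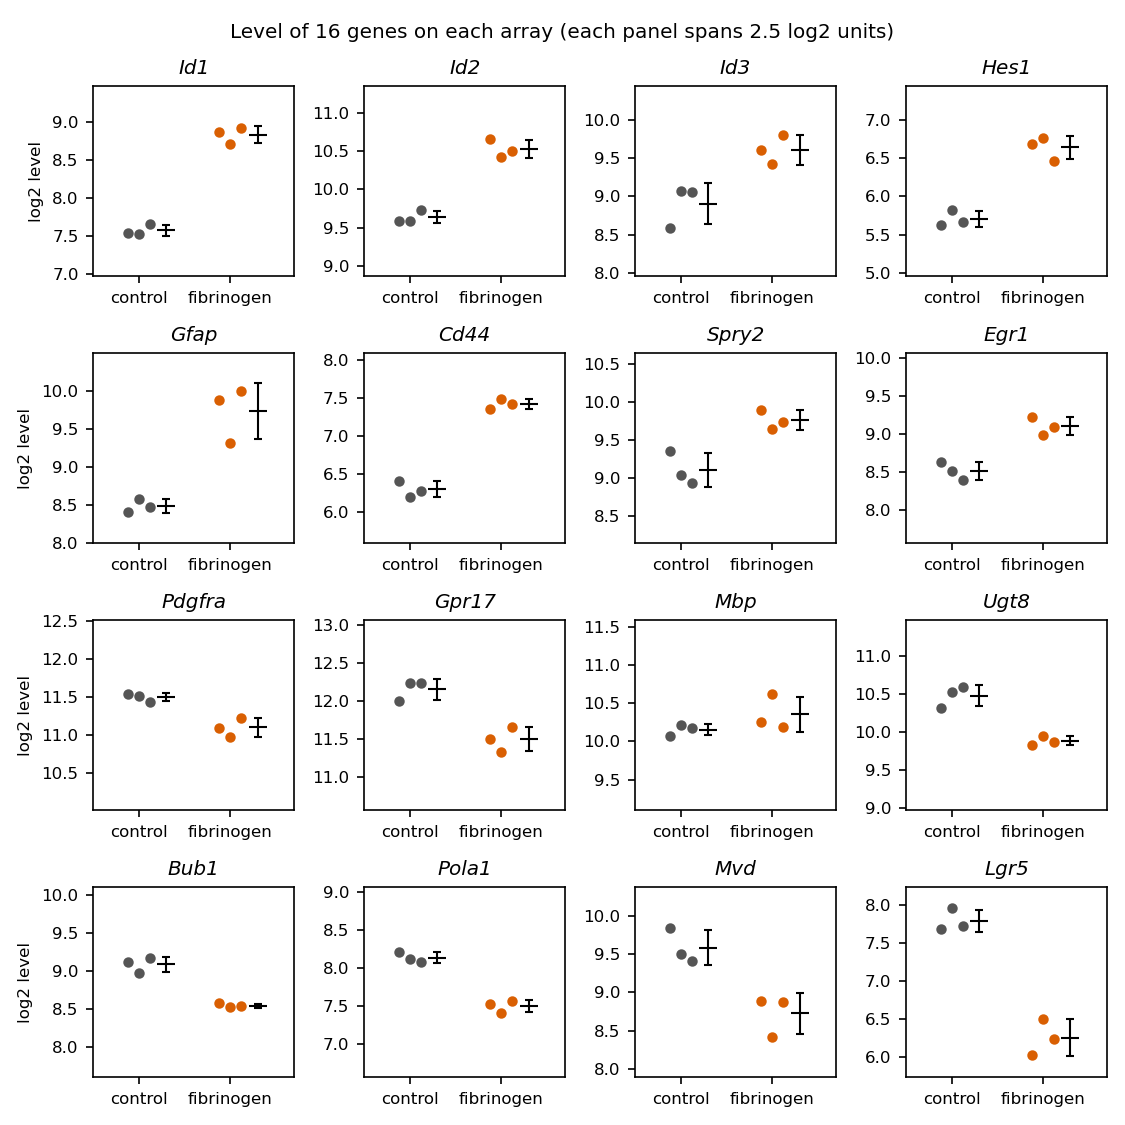
Log2 level of 16 named genes on each of the 6 arrays, in control cells (grey) and after 12 h of fibrinogen (orange), with the mean and SD of each group of 3 as a bar; each panel spans 2.5 log2 units. All fibrinogen values of Id1, Id2 and Id3 lie above the controls, those of Pdgfra and Gpr17 lie below, and those of Mbp overlap with the controls.

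Genes for BMP ligands and receptors did not shift as a group. Of 17 measured members 1 rose, the receptor gene Bmpr1a (log2 change 0.34 ± 0.07, SE), and 1 fell, the ligand gene Bmp7 (-0.43 ± 0.10), with 2 and 2 adjusted over the list alone (limma). The median log2 change was 0.0033 and the mean -0.02, with a downward camera statistic (adjusted p = 0.869). The call for Bmpr1a ended after median centring (log2 change 0.31), and both gene calls ended without any array but fibrinogen 2: without control 1, 2 and 3 and fibrinogen 1 and 3, the adjusted p was 0.166, 0.188, 0.104, 0.121 and 0.118 for Bmpr1a and 0.176, 0.0921, 0.181, 0.120 and 0.106 for Bmp7 (limma).

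Targets of TGF-beta and genes of the Notch pathway were shifted upward in camera (adjusted p = 0.00816 each), and Wnt targets were not. Both calls were lost with an estimated correlation (adjusted p = 0.113 for TGF-beta targets and 0.209 for Notch genes). Of 16 TGF-beta targets 1 rose and 0 fell in limma (2 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05): Pmepa1, a feedback inhibitor of TGF-beta signaling, by 0.84 ± 0.08 (SE). The median log2 change of that list was 0.085. Without fibrinogen 2, 2 of its members rose. Of 16 Notch genes 3 rose and 0 fell (5 and 1 both adjusted over the list alone and at an unadjusted p under 0.05), namely the effector Hes1 by 0.94 ± 0.10 (SE), Hey1, and Lfng, which modifies Notch receptors, by 0.48. The median was 0.13, and camera on ranks gave an adjusted p of 0.0638. Without fibrinogen 3 the median was 0.06. The call for Lfng ended without control 1, 2 or 3 or fibrinogen 1 (adjusted p = 0.0634, 0.0693, 0.0963 and 0.0546, limma), which left 2 Notch genes higher in each of these fits. Of 13 Wnt targets 1 rose and 1 fell (1 and 1 adjusted over the list alone), the transcription factor gene Lef1 by 0.51 ± 0.10 (SE) and Lgr5. The Wnt median was 0.04 and the mean -0.04, with an upward camera statistic (adjusted p = 0.460). Lef1 passed only with all arrays or without fibrinogen 3, and its adjusted p was 0.0873, 0.114 and 0.0688 without control 1, 2 and 3 and 0.0703 and 0.0519 without fibrinogen 1 and 2 (limma).

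Of 22 measured genes of the OPC state, 6 fell, 1 rose and 15 did not pass in limma (10 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.17. The list was shifted downward in camera (adjusted p = 0.00085), a call that was lost with an estimated correlation (adjusted p = 0.113). Brinp3 fell by 0.79 ± 0.07 (SE), the receptor gene Gpr17, which marks committed precursors, by 0.66 ± 0.10, the sialidase gene Neu4 by 0.65 ± 0.09 and Lims2, also in the myelin list, by 0.59 ± 0.11. Pdgfra, the receptor for PDGF that defines OPCs, fell by 0.40 ± 0.08 from a log2 level of 11.50 ± 0.05 to 11.10 ± 0.13 (SD, n = 3 each), to 0.760 of the control. Cspg4, also in the pericyte and fibroblast list, fell by 0.35 ± 0.08 (SE), a call that was lost in every fit that left out 1 array. The member that rose was the xylosyltransferase gene Xylt1 (0.41 ± 0.08), singled out after its values were seen. Olig2 was not analysed here. In the same arrays, 6 of 23 astrocyte genes rose. In fits without 1 array the OPC list kept a camera adjusted p of at most 0.00725, while 3, 2 and 2 members fell without control 1, 2 and 3, 3 without fibrinogen 1, and 0 rose in these fits or without fibrinogen 3. Pdgfra had adjusted p-values of 0.159, 0.159 and 0.114 without control 1, 2 and 3 and 0.111 and 0.0628 without fibrinogen 1 and 2, Lims2 of 0.105, 0.129, 0.102 and 0.0938 without control 1, 2, 3 and fibrinogen 1, and Gpr17 of 0.0690 and 0.0713 without control 2 and 3 (limma).

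Myelin and oligodendrocyte genes moved in both directions, with more falls than rises. Of 26 measured members 6 fell and 1 rose (8 and 2 adjusted over the list alone), with a median log2 change of -0.04. Evi2a fell by 0.90 ± 0.13 (SE), Fa2h and Ugt8, enzymes that make the galactolipids of myelin, fell by 0.65 ± 0.13 and 0.59 ± 0.09, and Ermn, a cytoskeletal protein of oligodendrocytes, rose by 0.91 ± 0.11. Mbp, a main protein of compact myelin, had a log2 level of 10.16 ± 0.08 in control and 10.36 ± 0.23 in fibrinogen cells (SD, n = 3 each), a difference of 0.20 ± 0.11 (SE) that did not pass (adjusted p = 0.459, limma). Its 2 probe sets gave 0.20 and 0.17, and without fibrinogen 2 the difference was 0.07. The downward shift of the list had an adjusted p of 0.0407 in camera and an adjusted p of 0.291 with an estimated correlation. It did not pass after median centring (0.0631), with the replicate number as a block (0.0574), on ranks (0.222) or in fry (0.0580). It was also lost without control 2 (0.0699), control 3 (0.0870), fibrinogen 2 (0.121) or fibrinogen 3 (0.0637), its median was -0.07 without control 1, -0.10 without fibrinogen 1 and -0.07 without fibrinogen 3, and the number of members that fell was 3, 1 and 1 without control 1, 2 and 3, and 2 rose without fibrinogen 2. Fa2h lost its call without control 1, 2 or 3 or fibrinogen 3 (adjusted p = 0.0631, 0.131, 0.114 and 0.0662), and Ugt8 without control 2 or 3 (0.0551 and 0.0514, limma).

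Of 23 measured astrocyte genes, 6 rose, 1 fell and 16 did not pass in limma (12 rose and 1 fell adjusted over the list alone), and the median log2 change was 0.22. The list was shifted upward in camera (adjusted p = 6.0e-07), a call that was lost with an estimated correlation (adjusted p = 0.0892). The estimate itself was -0.0307, so a high correlation between these genes does not account for the loss. Gfap rose by 1.24 ± 0.16 (SE), from a log2 level of 8.48 ± 0.09 to 9.73 ± 0.37 (SD, n = 3 each). Cd44 rose by 1.12 ± 0.08, Ndrg2 by 0.96 ± 0.10 and Cryab, a small heat shock protein, by 0.65 ± 0.08. The member that fell, Nes, which encodes an intermediate filament of progenitors and was singled out after its values were seen, passed in no fit without 1 array. Genes of reactive astrocytes were shifted upward too, with 2 of 28 measured members higher and 0 lower (3 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05), Hspb1 and the membrane protein gene Emp1, which rose by 0.89 ± 0.10. Their median was 0.08, with an adjusted p of 0.00292 in camera and an adjusted p of 0.113 with an estimated correlation. Without fibrinogen 2, 3 of them rose.

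**Figure D2:**
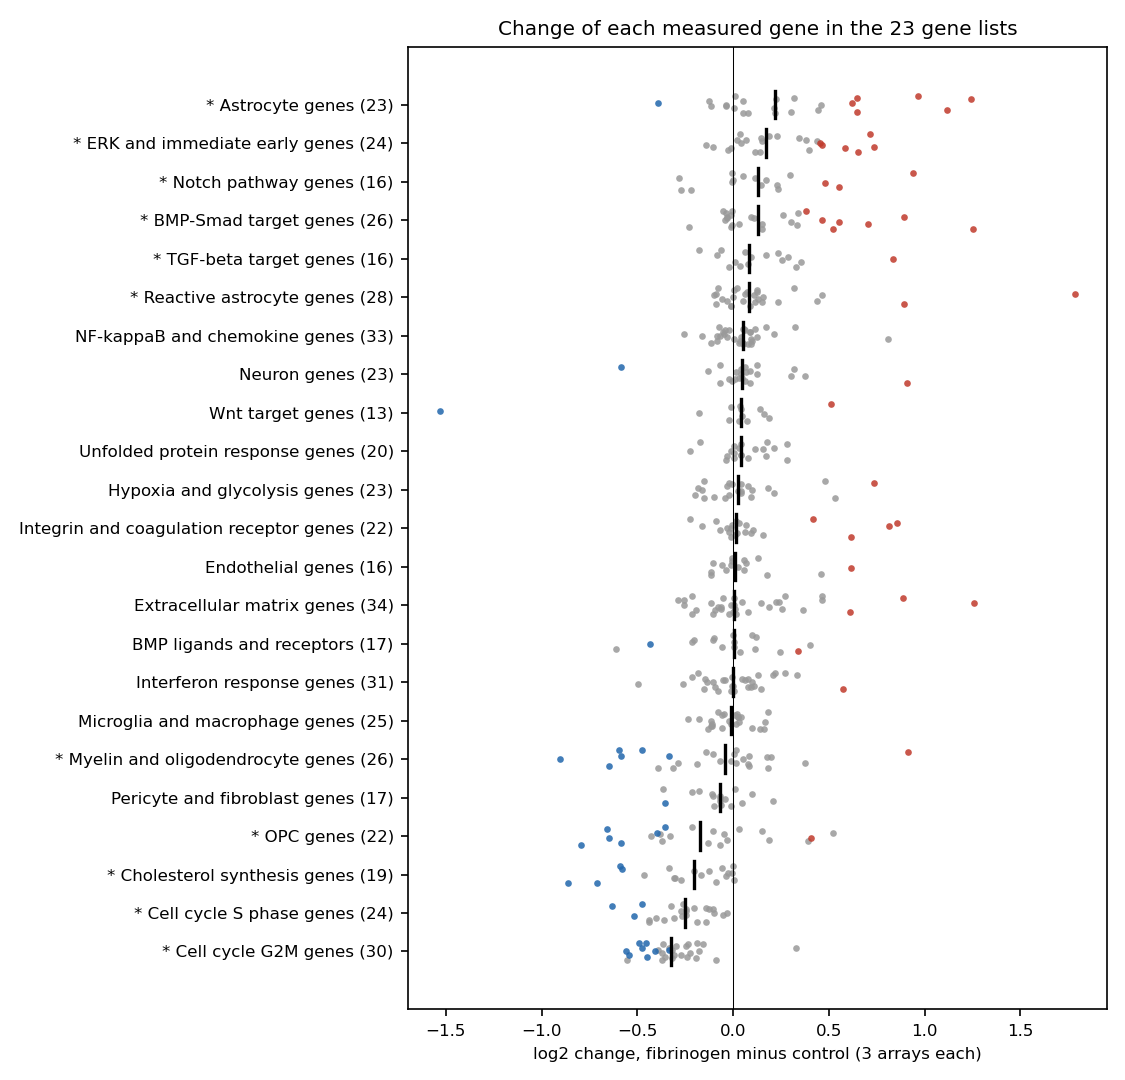
Log2 change with fibrinogen of every measured gene in the 23 gene lists, with the number of genes in brackets; red genes rose and blue genes fell (limma, adjusted p under 0.05), grey genes did not pass, black bars are medians, and a star marks a shift in camera with its preset correlation. Points are spread vertically only to separate them. The medians of the starred lists run from -0.33 for G2M genes to 0.22 for astrocyte genes.

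Markers of other cells that such a culture could hold did not shift in the main camera fit. Only 5 of 16 endothelial and 7 of 17 pericyte and fibroblast genes lay above the receptor percentile, so a shift could be missed there. For neuron genes this was 18 of 23, and their list passed upward in camera without genes under the 30th percentile (adjusted p = 0.0343). None of 25 microglia and macrophage genes passed in limma (0 adjusted over the list alone), and their median was -0.01 (camera adjusted p = 0.755); at an unadjusted p under 0.05, 1 of them passed, and 7 lay above the receptor percentile. The members with the largest differences were Ly86 (-0.24 ± 0.10, SE) and Cd53 (-0.18 ± 0.23), neither past the test nor above the receptor percentile. Without fibrinogen 1 they were -0.12 and 0.06, and without fibrinogen 2 that of Cd53 was -0.48. Of 23 neuron genes 1 rose and 1 fell, both over all genes and adjusted over the list alone: the neuropeptide gene Npy by 0.91 ± 0.14 and Gad2, which makes GABA, with a change of -0.58 ± 0.09 (median of the list 0.05, camera adjusted p = 0.160). Gad2 lay below the receptor percentile in both groups (5.35 and 4.77), where a log2 change is imprecise. Of 16 endothelial genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05), Podxl by 0.62 ± 0.09 (median 0.01, camera adjusted p = 0.368). Of 17 pericyte and fibroblast genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, 0 and 3 at an unadjusted p under 0.05), Cspg4, by 0.35 ± 0.08 (median -0.07, camera adjusted p = 0.0888). OPCs also express Cspg4, and its fall is counted in the OPC list too. This last list passed in the fit without fibrinogen 2, with an adjusted p of 0.0281. The calls for Npy ended without control 1 or 3 (adjusted p = 0.0556 and 0.0665), for Podxl likewise (0.0517 and 0.0561), for Gad2 without control 3 (0.0514), and for Cspg4 without any of the arrays, with 0.179, 0.173 and 0.119 without control 1, 2 and 3 and 0.109, 0.0670 and 0.0706 without fibrinogen 1, 2 and 3 (limma).

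The S phase and G2M lists were shifted downward in camera (adjusted p = 1.66e-09 and 5.78e-17). Neither call held with an estimated correlation (adjusted p = 0.238 and 0.113), which was itself high in the S phase list (0.497). All 24 measured S phase genes had a negative log2 change, with a median of -0.25, and 3 fell and 0 rose over all genes in limma (11 and 0 adjusted over the list alone, 12 and 0 at an unadjusted p under 0.05). Among them were Pola1, a subunit of the polymerase that primes DNA synthesis, which fell by 0.63 ± 0.08 (SE), and the replication fork genes Cdc45 and Mcm6, which fell by 0.52 ± 0.10 and 0.47 ± 0.10. Of 30 G2M genes 29 had a negative change, with a median of -0.33, and 8 fell and 0 rose over all genes (23 and 1 both adjusted over the list alone and at an unadjusted p under 0.05). The mitotic genes Kif20b, Bub1, Bub1b and Aurkb fell by 0.56 ± 0.09, 0.54 ± 0.08, 0.49 ± 0.09 and 0.48 ± 0.10. Fry gave an adjusted p of 0.0580 for the S phase list, and without control 1 its median was -0.17. The number of S phase genes that fell was 1 without control 1, control 2, fibrinogen 1 or fibrinogen 2, and that of G2M genes was 1 without control 1 and 2 without control 2, control 3 or fibrinogen 1. Pola1 and Bub1 kept their calls without each array, and Kif20b lost its call without control 1 or 3 (adjusted p = 0.0530 and 0.0604). Cdc45 (0.0882, 0.106, 0.0905 and 0.0586) and Bub1b (0.0924, 0.101, 0.0821 and 0.0561) lost theirs without control 1, control 2, fibrinogen 1 or fibrinogen 2. Mcm6 and Aurkb lost theirs without any array, with 0.118, 0.125 and 0.0688 for Mcm6 and 0.114, 0.0727 and 0.104 for Aurkb without control 1, 2 and 3, and 0.122, 0.0879 and 0.0738 for Mcm6 and 0.109, 0.0779 and 0.0501 for Aurkb without fibrinogen 1, 2 and 3 (limma).

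The cholesterol synthesis list was shifted downward in camera (adjusted p = 2.97e-06), but not in fry (adjusted p = 0.0794) or with an estimated correlation (adjusted p = 0.291). Of 19 measured members 4 fell, 0 rose and 15 did not pass in limma (6 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05), and the median log2 change was -0.20. Mvd, Ebp and Lss, enzymes of the sterol pathway, fell by 0.86 ± 0.15, 0.59 ± 0.13 and 0.58 ± 0.09 (SE), and Acat2, an acetyl-CoA acetyltransferase, fell by 0.71 ± 0.09. The number that fell was 2 without control 1 and 1 without control 2. Acat2 kept its call without each array, while Mvd lost its call without control 1 or 2 (adjusted p = 0.0725 and 0.0669), Lss without control 2 (0.0570), and Ebp without any array (0.102, 0.119 and 0.0606 without control 1, 2 and 3, and 0.113, 0.103 and 0.0701 without fibrinogen 1, 2 and 3, limma).

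The list of immediate early genes and feedback regulators of ERK signaling was shifted upward in camera (adjusted p = 4.36e-07), but not with an estimated correlation (adjusted p = 0.113). Of 24 measured members 6 rose, 0 fell and 18 did not pass in limma (11 and 0 adjusted over the list alone, 12 and 0 at an unadjusted p under 0.05), with a median log2 change of 0.17. The immediate early genes Ier2, Ier3 and Egr1 rose by 0.74 ± 0.10, 0.71 ± 0.09 and 0.59 ± 0.09 (SE), and Spry2, a feedback inhibitor of receptor tyrosine kinases, by 0.65 ± 0.12. The number that rose was 2 without control 2 or 3 and 3 without fibrinogen 1 or 3. The call for Spry2 ended without control 2, control 3, fibrinogen 1 or fibrinogen 3 (adjusted p = 0.108, 0.102, 0.0852 and 0.0655) and that for Egr1 without control 2 or 3 (0.0603 and 0.0647, limma).

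Some matrix and adhesion genes rose, without a shift of their lists. Of 34 matrix genes 3 rose and 0 fell in limma (8 and 0 adjusted over the list alone, 9 and 4 at an unadjusted p under 0.05), namely Bgn, the neural proteoglycan Ncan by 0.89 ± 0.08 (SE) and Sparc by 0.61 ± 0.07. The median was 0.01 (camera adjusted p = 0.0851), and without fibrinogen 2, 6 rose and 1 fell. Of 22 genes for integrins and coagulation receptors 4 rose and 0 fell (4 and 0 adjusted over the list alone, 4 and 2 at an unadjusted p under 0.05), with a median of 0.02 (camera adjusted p = 0.0682). The laminin receptor subunit Itga6 rose by 0.86 ± 0.07, tissue factor (F3), which starts coagulation, by 0.81 ± 0.12, Anxa2 by 0.61 ± 0.07 and Itgb5 by 0.42 ± 0.09. This list passed in camera without control 1 (0.0248), and in fry both lists did (0.00762 each). Without control 3, 2 members rose. The call for F3 ended without control 3 (0.0546), and that for Itgb5 ended after quantile normalization, median centring or cyclic loess and without control 1, 2 or 3 (0.0996, 0.196 and 0.164) or fibrinogen 2 or 3 (0.0766 and 0.119, limma).

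The inflammatory lists and those of the unfolded protein response and hypoxia did not shift in the main camera fit. Heat shock genes had no list of their own, so their response as a group was not tested. Only 18 of 33 NF-kappaB and chemokine genes and 17 of 31 interferon response genes lay above the receptor percentile, so a shift could be missed there. None of the 33 passed in limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), and their median log2 change was 0.05 (camera adjusted p = 0.260). Without genes under the 30th percentile this list passed upward in camera (adjusted p = 0.0275). The chemokine gene Ccl2 had a difference of 0.81 ± 0.25 (SE) and the inhibitor gene Nfkbia of 0.32 ± 0.10, neither past the test (adjusted p = 0.141 and 0.140, limma). Without fibrinogen 2, Nfkbia passed (0.0336) and the difference of Ccl2 was 0.49. Of 31 interferon response genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, 4 and 2 at an unadjusted p under 0.05), Usp18 by 0.57 ± 0.08 from a level of 2.92 ± 0.03 (SD, n = 3), below the receptor percentile (median of the list 0.00). The camera adjusted p was 0.513, while fry gave 0.0363. None of 20 genes of the unfolded protein response passed in limma (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), with a median of 0.04 (camera adjusted p = 0.151, and 0.0297 without control 1). Asns and Ddit3 had differences of 0.28 ± 0.10 and 0.28 ± 0.12, neither past the test, and that of Ddit3 was 0.13 without fibrinogen 2. Of 23 hypoxia and glycolysis genes 1 rose and 0 fell (3 and 0 adjusted over the list alone, 4 and 1 at an unadjusted p under 0.05), the oxygen sensor gene Egln3 by 0.74 ± 0.08 (median 0.02, camera adjusted p = 0.372).

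In all, camera with its preset correlation called 11 of the 23 lists, 6 upward and 5 downward. The medians of the other 12 lists lay between -0.14 and 0.08 in every fit without 1 array. With an estimated correlation camera called 0, and 7 had an unadjusted p under 0.05. The estimate lay under the preset 0.01 for BMP targets (0.00467), TGF-beta targets (-0.0549), astrocyte genes (-0.0307) and reactive astrocyte genes (-0.0177). It lay above 0.01 for the other called lists. In the lists under 0.01 the unadjusted p rose through the fewer degrees of freedom of that setting, not through correlation. Fry called 11, but lost the S phase, cholesterol and myelin lists and gained the matrix, integrin and interferon lists. With genes under the 30th percentile of levels left out, camera also called the matrix (0.0275), integrin (0.00428), NF-kappaB (0.0275) and neuron (0.0343) lists upward, and the integrin list passed with array weights (0.0474) or an intensity trend (0.0493). Fry asks whether the genes of a list move one way on balance, and camera whether they move more than other genes.

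The fibrinogen arrays differed more from each other than the controls did, mainly because of fibrinogen 2. Pearson's r across genes, which are not independent replicates, was 0.997 for each pair of controls and for fibrinogen 1 and 3, and 0.994 for fibrinogen 2 with each of the other fibrinogen arrays. The SD of all genes about their group mean was 0.146 for fibrinogen 2, against 0.114 and 0.110 for fibrinogen 1 and 3 and at most 0.0939 for a control. That mean includes fibrinogen 2, which widens the SDs of fibrinogen 1 and 3. The SD of the difference between fibrinogen 1 and 3 was 0.169, against 0.151 to 0.164 for pairs of controls. For fibrinogen 2 it was 0.238 with fibrinogen 1 and 0.232 with fibrinogen 3. Without fibrinogen 2, 436 genes changed, 263 higher and 173 lower, of which 193 and 135 were among the 252 and 180 genes called with all arrays. The median log2 change of the 252 genes that rose was 0.57, 0.55 and 0.52 in fibrinogen 1, 2 and 3, and that of the 180 genes that fell was -0.51, -0.53 and -0.47. These genes were called on the same arrays by a test that favours genes alike on all 3. The medians therefore do not show that fibrinogen 2 responded like the others. Of the 68 named genes that changed, 41 kept their call in each fit that left out 1 array.

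**Figure D3:**
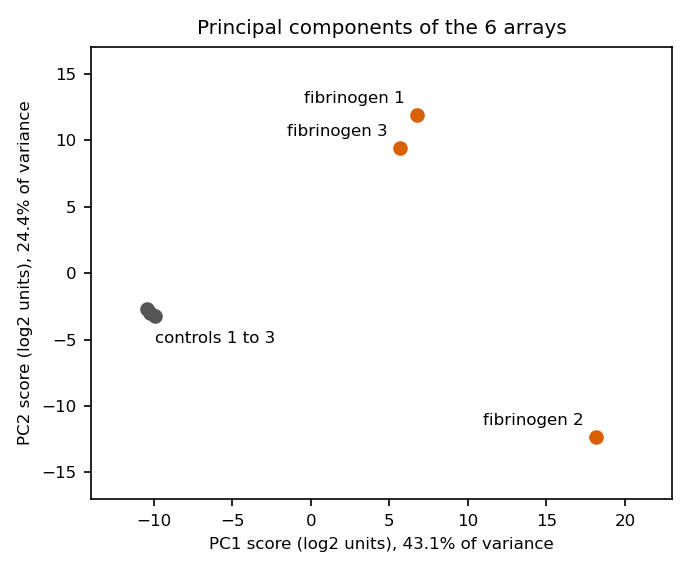
Scores of the 6 arrays on the first (43.1% of variance) and second (24.4%) principal components of the 13949 genes, in log2 units. The controls lie between -10.4 and -9.91 on the first component, fibrinogen 1 and 3 lie at 6.73 and 5.69, and fibrinogen 2 lies at 18.2 and on the other side of the second component.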

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

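The alternatives were planned, apart from the receptor filter and the list counts without fibrinogen 2, which were chosen after seeing the data. The 432 changed genes (252 higher, 180 lower) became 659 (383 and 276) with array weights, 135 (88 and 47) at an adjusted p under 0.01, 179 (114 and 65) with a 1.5-fold minimum and 75 (48 and 27) in limma's treat against 1.2-fold, stricter thresholds by construction. Leaving out 1 array gave 151 to 436 genes (96 to 263 higher, 55 to 173 lower), with fewer arrays in each fit: 151 without control 3 and 436 without fibrinogen 2. All other settings stayed within 1.5 times the count. In all 432 genes the values of the 2 groups did not overlap, so leaving out an array could not turn their direction. The median change of all genes was -0.0033, and -0.03 after median centring.

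The estimated correlation left 0 lists shifted (7 at an unadjusted p under 0.05; fry 11), and BMP targets at 0.0892. The myelin list had 0.0631 after median centring, 0.291 with an estimated correlation, 0.222 on ranks, 0.0580 in fry, and 0.0112 to 0.121 without 1 array. Statistics turned in direction for BMP ligands and receptors with the 30th percentile filter (0.633) and the receptor filter (0.649), and for microglia genes without control 1 (0.926) or fibrinogen 1 (0.979), in a range of 0.485 to 0.979 without 1 array. Cd53 ranged from -0.48 to 0.062 without 1 array. None of these passed, and the cause was not tested. Of the 68 called named genes, each filter on dim genes tested 65, and the other thresholds were not applied to them. Under each normalization, filter, variance model, probe set mean and replicate block that gave them a value, 56 kept their call and none reversed. Leaving out 1 array could not reverse them, since their groups did not overlap. eBayes with a robust prior was not run for lists, since camera has no such option. Signal over background limits the 4066 genes with a mean level not above the receptor percentile.

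Arrays share only a replicate number: same-numbered arrays deviated from their group means with r = 0.0278, 0.0217 and 0.0109 over genes. With the replicate block, 315 genes passed (195 higher, 120 lower) and 10 lists, BMP targets had 7.70e-06, the myelin list 0.0574, and 12 of the 68 named genes lost their call.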

Other observations

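The 13 gene families, the genes of the first 2 paragraphs, Aqp4 and Gja1, and the tests of the last 2 paragraphs, were chosen only after the result was seen; the counts of other splits were planned. Several further genes with large changes, from the ranks after the 10 largest in each direction, belonged to no list. Lgals3 and Pdpn, which reactive glia express, rose by 1.06 ± 0.12 and 1.05 ± 0.12 (SE), the death receptor gene Fas by 1.03 ± 0.13, the cyclin gene Ccnd2 by 0.93 ± 0.11, the cytokine feedback gene Socs2 by 0.85 ± 0.08 and the chemokine receptor gene Cxcr4 by 0.85 ± 0.10, where Ackr3, the other receptor for the same ligand, fell by 1.28. The Wnt modulator gene Sfrp2 fell by 1.10 ± 0.14, the phosphatase gene Ptpre by 1.02 ± 0.07, the lipoprotein receptor gene Scarb1 by 0.73 ± 0.08 and Acss2, which makes acetyl-CoA from acetate, by 0.72 ± 0.11. These calls held in limma in each fit without 1 array. The caveolin genes Cav1 and Cav2 rose together, by 1.42 ± 0.07 and 0.72 ± 0.15, while the 10 caveola genes as a family had a camera adjusted p of 0.0812 over the 13 families, and Cav2 lost its call without control 1 or 3 or fibrinogen 1 or 2 (adjusted p = 0.131, 0.131, 0.115 and 0.0954, limma).

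Of the 13 families, histone genes were shifted down, with 2 of 19 lower, H2bc12 by 0.78 ± 0.15 and H1f5 by 0.73 ± 0.11 (median -0.11, camera adjusted p = 0.00705, adjusted p = 0.344 with an estimated correlation). H2bc12 had adjusted p-values of 0.118, 0.107 and 0.0990 and H1f5 of 0.0617, 0.0527 and 0.0542 without control 1, 2 and 3 (limma). GABA-A receptor subunit genes were shifted up, with Gabra4 higher by 1.06 ± 0.13 and Gabrg3 by 0.36 ± 0.08 among 16 (adjusted p = 0.0139 in camera, adjusted p = 0.344 with an estimated correlation, 0.0798 without fibrinogen 2). Of the 16, 5 lay above the receptor percentile, and Gabrg3, at 5.30 in controls, lay below it and lost its call without control 1, 2 or 3 or fibrinogen 2 or 3 (adjusted p = 0.148, 0.157, 0.141, 0.0602 and 0.113, limma), which left 1 higher without fibrinogen 2. Proteasome genes had a median of -0.09 with 1 of 37 lower, Psmb10 by 0.52, and a median of -0.06 without control 1 and -0.03 without fibrinogen 2 (adjusted p = 0.0139 in camera, adjusted p = 0.683 with an estimated correlation, 0.266 without fibrinogen 2), and Psmb10 had adjusted p-values of 0.0579 and 0.0546 without control 2 and 3 (limma). Ribosomal protein genes (70), mitochondrial complex I genes (37), olfactory and vomeronasal receptor genes (878 and 78), annexin, S100, ephrin, semaphorin and glutamate receptor genes did not shift in camera. Of 10131 probe sets with no gene name here, 105 were higher and 56 lower in a fit of all probe sets.

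The 6 arrays can be split into 3 and 3 in 10 ways, so the share of splits with as large a result cannot fall under 0.05. 1 of the 10, the real one, gave 432 changed genes, and the highest of the other splits gave 0 in limma, with 373 to 618 genes at an unadjusted p under 0.05 in these against 2173. Each other split has control and fibrinogen arrays on both sides. A difference between the groups would widen the spread within its sides and lower its gene counts, so the contrast with the real split is overstated. For the gene lists in camera, 1 of the 10 gave as many as 11, the real one, and the highest of the others gave 4.

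Of the OPC genes 6 of 22 fell and 1 rose, and of the astrocyte genes 6 of 23 rose and 1 fell, list shifts that were lost with an estimated correlation (adjusted p = 0.113 and 0.0892). A change in cell shares alone, with each gene expressed in 1 cell type, would give each list a common change if the arrays reported all changes alike. Yet the changes were unequal among the 23 astrocyte genes (Cochran's Q of 455 on 22 degrees of freedom, with -0.04 ± 0.08 for Gja1, 0.01 ± 0.07 for Aqp4 and 1.24 ± 0.16 for Gfap, SE) and the 22 OPC genes (302 on 21). This argues against shares alone only under that condition, since normalization can compress changes unequally, which was not tested. A larger share of astrocytes in part stays open, since the median of the astrocyte genes was 0.22 (bootstrap 95% interval over genes 0.05 to 0.46) and levels that OPCs supply would make their rises unequal. This interval and the next measure the spread among listed genes, not that between cultures. A smaller share of oligodendrocyte lineage cells would raise the markers of all other types alike, and among genes above the receptor percentile the median of 22 astrocyte genes exceeded that of 36 genes of microglia, neurons, endothelial cells, pericytes and fibroblasts by 0.19 (interval -0.01 to 0.44, which includes 0). How much of each level came from OPCs is not known, so a part played by either share and a change within OPCs with fibrinogen, which may be the source and was not tested, cannot be told apart.

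Fibrinogen 2 lay apart from the other arrays of its group. A stronger response to fibrinogen in that array would make its excess over 1 other array follow the response of the remaining one. The larger of the 2 correlations over genes was -0.0195 (the other -0.0344). A difference that fibrinogen 1 and 3 share and fibrinogen 2 lacks would lower both correlations. On the second principal component fibrinogen 2 lay at -12.3, against 11.9 and 9.40, and on the first at 18.2, against 6.73 and 5.69. These correlations therefore cannot decide, and a stronger response stays open. Cyclic loess left its SD about the group mean at 0.145, against at most 0.113 for the others, which argues against a smooth distortion by intensity. Noise of dim probe sets is argued against too, since the ratio of its SD to the larger of the others was 1.68 for genes above a level of 10 and 1.01 for those below the receptor percentile. RNA quality, handling or a different cell mix may be behind it, none of which was tested. Fibrinogen SDs, which include fibrinogen 2, exceeded control SDs in 64.5% of all genes and 81.3% of the 1124 genes above a level of 10.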
